A study of Mus musculus with 6 samples.

How the data were processed

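Livers were compared in 2 groups named by the labels' genotype, 3 WT and 3 tamoxifen-induced Nek7 whole-body knockout (iKO). Per the labels' protocols, tissue was frozen in liquid nitrogen and RNA was extracted with Trizol. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the mouse build mm9. The authors deposited 1 table of 17441 genes with expected counts, FPKM and TPM for each library. The deposited expected counts are RSEM-style estimates that need not be whole, between 64.9% and 68.3% of them being whole within 0.001. The FPKM values the authors deposited are scaled by library size and transcript length, and the TPM values the authors deposited are scaled to a common total; neither removes a shift caused by a few abundant genes. Whether reads were counted by strand is not given in the sources used here. The reference at hand is of another build than mm9, so no coordinates are printed, and it served for gene names and transcript sequence.

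Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM normalization, robust quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05, no fold threshold. This left 13160 genes. CPM values are TMM-normalized, standard errors are the log2 fold change over the square root of F, and the factors ran from 0.780 (iKO 1) to 1.18 (WT 2). A "called" gene or list passed adjusted p 0.05. RSEM can split reads between near-identical genes and between overlapping genes, and such levels are less certain. At these totals per library (18139500 to 19912000), counting error is small beside the spread between livers except for genes near 1 CPM; a count of 0 allows 3 counts, and such limits cover counting error only.

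The gene lists, 33 of biology and 12 of cell type markers, and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 43 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The rule names Nek7; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups; up to 4 members of each called list in the direction of its call; and up to 2 called members of every other list. In the ranking, predicted genes without a symbol (63) and genes sharing reads with near-identical copies were passed over. The sign used for shared reads, expected counts not whole in all 6 libraries (474 genes), was chosen after seeing the data. Genes named outside the ranking can carry this sign, among them Mup1, Mup20, Cyp4a12b, Pck1, Irgm2, Gbp6, Ngfr and Tubb2a. Of 118 genes named by the rule, those most useful to the account are printed. Other members named among called genes of a list, and Nek6, Nlrp3, Cyp2e1, Glul, Mup1, Mup20, Cyp4a12b, Elovl3, Gsta3, Gstp1, Gstp2, the clock genes outside the rule and the Y-linked genes, were chosen after their values were seen. Of the 13160 genes 39.0% had no overlap between the groups, where chance gives 10%.

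Alternatives listed before the data were examined were RLE and upper-quartile factors, no filter beyond 1 count in 1 library, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, leaving out each library, camera with an estimated correlation, and fry. Added after seeing the data were a term for whether a library holds Y-linked reads, the 4 libraries with such reads alone, a correction for transcript length, and both corrections together. A library was taken to hold Y-linked reads when Ddx3y and Kdm5d together gave over 10 expected counts; WT 2 and WT 3 gave 0 of both, and 5.99 and 4 of Eif2s3y. With the Y-linked term the contrast rests on WT 1 as the WT library above that bound. Effective lengths were taken from expected counts and FPKM where FPKM reached 0.2, which gave a length to 98.7% of tested genes, and the lowess trend (span 0.3) of log2 CPM over log2 length in each library entered the model as an offset. Term enrichment used the pathway and cellular component terms in the deposited table, terms of 10 to 300 tested genes, a one-sided hypergeometric (Fisher) test and the tested genes with any term as background. Sequence comparison used blastn 2.17.0.

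The fit was tested on simulated data with the real means, library sizes and dispersions for the iKO against WT comparison, on 13002 genes. Of 100 genes changed 2-fold, 53% were recovered, and of 100 changed 4-fold, 92%, with 0 in the wrong direction; 12 of 166 calls were false. A simulated list with all members 2-fold higher was called, and 0 of 40 unchanged lists were. Genes were simulated independently and the unchanged lists held random genes, so false list calls from correlated genes could not show here. A length trend put into 1 library gave a rho of -0.37 before the correction and about 0 after it.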

Results

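Gene expression was measured by RNA-seq in 6 mouse livers, 3 labelled wild type (WT) and 3 labelled Nek7 iKO. The iKO label stands for a whole-body, tamoxifen-inducible knockout of Nek7, a kinase with roles in mitosis and in assembly of the NLRP3 inflammasome. All 6 livers were taken 10 days after tamoxifen. The comparison asks what the liver transcriptome of the labelled knockout looks like beside WT, and the title of the series names acetaminophen injury and cell cycle regulation as the setting. The labels number the livers within a group and say no more about the animals, so p-values of single genes measure the spread between these samples. Camera at the preset correlation, the Fisher test and the permutation test of marker genes compare genes with genes. Their p-values do not measure that spread. Library totals ran from 18139500 to 19912000 expected counts (to 6 significant digits), and no pair of libraries agreed within sampling noise. Albumin transcripts took between 5.18% and 10.7% of the counts of a library.

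Nek7 (gene ID 59125), the gene the knockout label names, was read at 44.1 ± 10.1 CPM in WT (SD, n = 3) and at 38.0 ± 10.6 CPM in the livers labelled iKO (SD, n = 3). The single libraries held 55.5, 40.5 and 36.3 CPM in WT and 50.2, 32.8 and 31.0 CPM in those labelled iKO. The log2 fold change was -0.22 (SE 0.23, adjusted p = 0.541 by edgeR's quasi-likelihood test), which puts Nek7 at 86.1% of WT with a 95% interval of 60.3% to 123%. A 2-sided exact permutation test of the log2 values gave p = 0.5, where 3 against 3 livers can give no p below 0.1. The gene total counts every exon, so it does not show whether a deleted part of the gene is missing. Expected counts of Nek7 were not whole in all 6 libraries, so reads may be shared with other genes and its level is less certain. The libraries are called "labelled iKO" throughout because the gene itself does not set them apart. Its close relative Nek6 was at 56.4 ± 6.19 and 61.6 ± 1.70 CPM (SD, n = 3 each; adjusted p = 0.591). Of the 10 tested Nek kinases and Nek7 partners, 0 were called (adjusted over the list alone, 0), and camera did not call the list (adjusted p = 0.601).

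Sex-linked genes cut across the labels. Y-linked Ddx3y gave 817 expected counts in WT 1 and 432, 640 and 670 in the libraries labelled iKO. It gave 0 counts in WT 2 and 0 in WT 3, which allows up to 0.133 and 0.145 CPM (3 counts). Kdm5d, also Y-linked, followed with 296, 141, 221 and 213 counts against 0 and 0. Y-linked Eif2s3y gave 699, 212, 615 and 554 expected counts in the same 4 libraries and 5.99 and 4 in WT 2 and WT 3. Libraries with over 10 expected counts of Ddx3y and Kdm5d together are those said below to hold Y-linked reads. The female-biased cytochrome Cyp2b13 stood at 269 and 293 CPM in WT 2 and WT 3, at 0.159 CPM in WT 1 and at 0, 0.590 and 0 CPM in the libraries labelled iKO. The male-biased urinary protein gene Mup20 stood at 6510 CPM in WT 1 and 162 and 111 CPM in WT 2 and WT 3, against 7440, 7087 and 5896 CPM in the libraries labelled iKO. Male-biased Cyp4a12b, at 120, 0.133 and 0.0967 CPM in WT and 64.9, 52.4 and 41.2 CPM in those labelled iKO, followed Mup20. Male-biased Mup1 stood at 2466, 6.30 and 14.4 CPM in WT and at 2186, 324 and 11.8 CPM in those labelled iKO. Elovl3, also male-biased, stood at 407, 2.66 and 4.59 CPM and at 164, 10.1 and 2.33 CPM. Male-biased genes were thus mixed in iKO 2 and iKO 3. By the Y-linked genes, Cyp2b13 and Mup20, WT 2 and WT 3 read as female livers and the other 4 libraries as male, though the labels give no sex. The contrast of the labelled groups therefore mixes apparent sex with the knockout label. Camera called the 16 tested female-biased genes lower (adjusted p = 0.0234; adjusted p = 0.831 with an estimated correlation) with 0 members called, adjusted over the list alone 0. That list call ended without WT 2 (adjusted p = 0.0704), without WT 3 (0.118) and without iKO 1 (0.0819). It turned to higher with a term for Y-linked reads (camera adjusted p = 0.00132, or 0.898 with an estimated correlation). The 16 tested male-biased genes had a median log2 fold change of 0.38, 0 called members, adjusted over the list alone 0, and no list call (adjusted p = 0.173). With the Y-linked term their median was -0.98 and camera called the list lower (adjusted p = 0.00213; adjusted p = 0.898 with an estimated correlation).

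**Figure D1:**
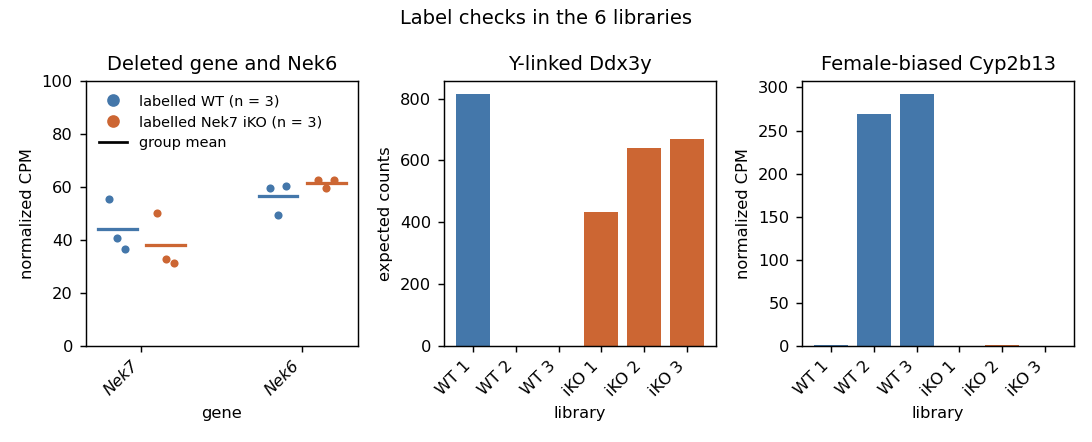
Normalized CPM of Nek7 and Nek6 per library with group means (left), expected counts of Y-linked Ddx3y per library (middle) and normalized CPM of Cyp2b13 per library (right), in 3 libraries labelled WT and 3 labelled Nek7 iKO. The Nek7 points of the 2 groups overlap, and WT 2 and WT 3 hold 0 Ddx3y counts and 269 and 293 CPM of Cyp2b13.

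Clock genes were among the largest differences between the labelled groups, and Dbp, Ciart and Usp2 had the 3 largest rises of all called genes. Dbp (gene ID 13170), a clock output transcription factor, was 1.44 ± 0.756 CPM in WT and 128 ± 24.6 CPM in the livers labelled iKO (SD, n = 3 each). That is a log2 fold change of 6.47 (SE 0.37, adjusted p = 0.000153). The repressor Ciart rose by 6.26 (SE 0.41), the deubiquitinase Usp2 by 5.18 (SE 0.34), Per1 by 2.99 (SE 0.49), Per3 by 2.89 (SE 0.36), Per2 by 2.43 (SE 0.38) and Tef by 2.05 (SE 0.24) on the log2 scale. Arntl, Npas2 and Cry1 went the other way. Arntl, which encodes BMAL1, fell from 31.4 ± 0.962 to 2.68 ± 1.15 CPM (SD, n = 3 each; adjusted p = 0.000271). Npas2 fell from 16.0 ± 2.48 to 0.857 ± 0.532 CPM (SD, n = 3 each; adjusted p = 0.000311). The repressor Cry1 fell by 1.19 (SE 0.31, adjusted p = 0.0341) on the log2 scale, a call that ended without WT 1, WT 2, iKO 1 or iKO 2 (up to 0.128, without WT 2). Clock, the partner of BMAL1, was not called (adjusted p = 0.0614). Of the 20 tested clock genes, 10 rose, 3 fell and 7 were not called, and adjusted over the list alone the counts were 11 and 4. Camera called the list higher (adjusted p = 2.03e-07; adjusted p = 0.42 with an estimated correlation). Dbp shares exon sequence with an overlapping gene in the reference annotation and its expected counts were not whole in all 6 libraries, so its level is less certain. Expected counts of Arntl were not whole in 4 libraries and those of Npas2 in 0. With a term for Y-linked reads, all 13 called clock genes kept their direction and 7 kept their call. The Per1 call ended without iKO 1 (adjusted p = 0.0547).

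**Figure D2:**
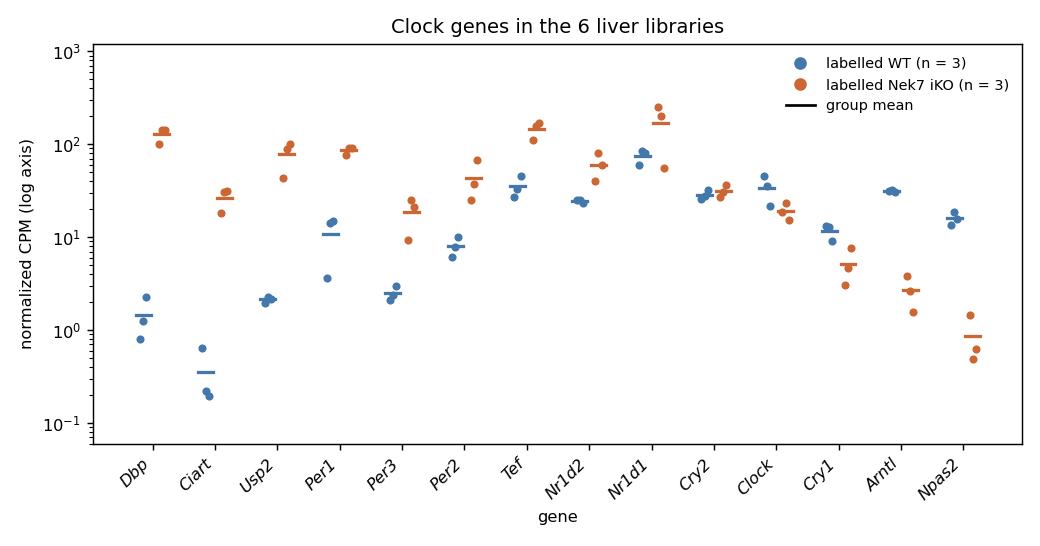
Normalized CPM of 14 clock genes in each library on a log axis, 3 libraries labelled WT and 3 labelled Nek7 iKO, with group means as lines. Dbp goes from 1.44 to 128 CPM on average and Arntl from 31.4 to 2.68 CPM.

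Over the whole transcriptome, 2024 of 13160 tested genes were called, 962 higher and 1062 lower in the livers labelled iKO. The labels give no hour of collection, so these calls could include differences by time of day, which was not tested. Besides Ciart, Usp2 and the clock repressor Bhlhe41, the largest rises were Ttll8, Noct, a deadenylase, Mt2, Lpin1, a phosphatidic acid phosphatase, Mt1, the kinase gene Plk3 and Alas1, the first enzyme of heme synthesis. Lpin1 went from 51.3 ± 25.6 to 889 ± 289 CPM (SD, n = 3 each), and Alas1 rose by 3.87 (SE 0.29) on the log2 scale. The metallothioneins Mt1 and Mt2 rose by 4.08 (SE 0.80) and 4.25 (SE 0.96) on the log2 scale, and their values spread widely, 1529 ± 1176 and 1369 ± 1118 CPM in the livers labelled iKO (SD, n = 3). The largest falls were Mpo, the lysyl oxidase gene Loxl4, Npas2, Ltf, Atp2b2, Arntl, Ngp, Ccn4, Pcdh18 and Tcf24. Loxl4 went from 21.9 ± 7.72 to 0.809 ± 0.224 CPM (SD, n = 3 each; adjusted p = 0.000191). Among these 20 genes the calls of Mt2, Mt1, Ltf, Atp2b2, Ngp and Tcf24 ended when 1 of several libraries was left out, with adjusted p up to 0.182 for Ngp without iKO 1 and up to 0.135 for Mt2 without WT 2. Calls numbered 491 without WT 2, 908 without WT 3 and 946 without iKO 3, and 465 genes were called in all 6 fits that left out 1 library. With a term for Y-linked reads the count was 184, 78 higher and 106 lower, of which 174 were also called without the term. In the 4 libraries with Y-linked reads the count was 143. The limma fit of log2(FPKM + 1), which uses no TMM factors, split 1352 calls into 421 higher and 931 lower. Fold changes also followed transcript length: across genes, which are not independent replicates, Spearman's rho of log2 fold change against effective length was -0.36. In the quintile with the shortest transcripts (2599 genes), 406 were called higher and 57 lower. In the quintile with the longest, 83 were called higher and 383 lower.

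The stellate cell and matrix lists were called lower in the livers labelled iKO. Lrat, which makes the retinyl esters that stellate cells store, went from 27.5 ± 11.6 to 3.36 ± 0.209 CPM (SD, n = 3 each), a log2 fold change of -3.03 (SE 0.29, adjusted p = 0.000678). Reln fell by 2.47 (SE 0.24) on the log2 scale, and Ngfr went from 10.8 ± 0.997 to 1.67 ± 0.726 CPM (SD, n = 3 each). Of 20 tested stellate cell and fibroblast markers, 15 fell and 0 rose, with 17 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.15e-13; adjusted p = 0.661 with an estimated correlation). The list's median log2 fold change was -1.42, -1.37 after correction for transcript length, and -0.88 with a term for Y-linked reads, where 3 members were called. Of 38 extracellular matrix genes 19 fell, among them Col5a1, Fbn1, Dcn and Col14a1. Adjusted over the list alone, 25 fell (camera adjusted p = 9.5e-11; adjusted p = 0.729 with an estimated correlation). The median of -1.19 became -0.51 with the Y-linked term, where 0 members were called.

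Markers of other non-parenchymal cells moved unequally. Of 25 Kupffer cell and macrophage markers 7 fell, 9 adjusted over the list alone, and camera called the list (adjusted p = 0.00021; adjusted p = 0.729 with an estimated correlation). Adgre1, which encodes F4/80, went from 22.5 ± 6.36 to 6.03 ± 2.08 CPM (SD, n = 3 each). Its call held whichever library was left out. The other Kupffer cell calls each ended in at least 1 such fit (adjusted p up to 0.148, Clec4f without WT 2). Of 24 sinusoidal endothelial markers 7 fell, 11 adjusted over the list alone, with a median of -0.86 (camera adjusted p = 1.34e-06, or 0.729 with an estimated correlation). Each of these 7 calls ended in at least 1 fit that left out 1 library (adjusted p up to 0.163, Cdh5 without WT 2). With the Y-linked term the endothelial median was -0.46 with 0 members called (camera adjusted p = 0.0038, or 0.898 with an estimated correlation). After the length correction it was -0.93 with 2 members called (camera adjusted p = 2.92e-06). Of 15 neutrophil markers 5 fell, all of them genes of granule proteins (Mpo, Elane, Camp, Ltf and Ngp), with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.815 with an estimated correlation). The neutrophil call ended without WT 3 (adjusted p = 0.0599), without iKO 1 (0.106) and without iKO 2 (0.154). The Elane call ended without WT 3 (adjusted p = 0.0633), iKO 2 (0.0531) or iKO 3 (0.0592), and the Camp call without WT 3 (0.0643) or any 1 of the libraries labelled iKO (up to 0.0699). With the term for Y-linked reads the Kupffer cell median went from -0.61 to 0.01 and the neutrophil median from -1.04 to -0.18, and neither list was called. After the length correction these medians were -0.77 and -1.69, and both lists were called lower (adjusted p = 2.44e-06 and 0.000654). T and NK cell markers had a median of 0.07 with 0 of 17 called, and cholangiocyte markers a median of 0.15 with 1 of 18 higher (Onecut1, also on the hepatocyte list) and 1 lower (Pkhd1), the same counts as adjusted over the list alone. Neither list was called (adjusted p = 0.886 and 0.915). The Onecut1 call held only without iKO 3 (adjusted p up to 0.157, without WT 2), and the Pkhd1 call only without WT 1 or iKO 2 (up to 0.154, without WT 2). B cell markers had 1 of 10 lower (Bank1, adjusted p of the list 0.115), erythroid markers 0 of 9 called (0.886), and muscle markers 2 of 6 lower (Des and Tagln; 0.418), with the same counts adjusted over the list alone for each of these lists. The B cell list was called lower after the length correction (adjusted p = 0.0342). The calls of Bank1 and Des held only without WT 1 (adjusted p up to 0.181 for Bank1 without WT 2 and 0.162 for Des without WT 3), and the Tagln call ended without WT 2 (0.0655), WT 3 (0.0551) or iKO 3 (0.0529). Of 5 adipocyte markers Plin4 and Cidec rose, by 2.71 (SE 0.22) and 2.41 (SE 0.39) on the log2 scale, while Fabp4 stood at 3.89 and 4.21 CPM; 2 were higher and 1 lower adjusted over the list alone. The adipocyte call (adjusted p = 0.0287; adjusted p = 0.661 with an estimated correlation) ended without WT 2 (0.0537), without WT 3 (0.0577) and without iKO 1 (0.209). It also ended with the Y-linked term (adjusted p = 0.176, median from 0.11 to -0.01) and after the length correction (0.0655, median -0.36). Pancreatic acinar markers (2 tested, Cela2a higher) and mesothelial markers (1 tested, Wt1 lower) were too few for a list test, and both genes were also called adjusted over the list alone. The Cela2a call ended without WT 2 (adjusted p = 0.0589).

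The list of interferon-stimulated genes was called lower. Irgm2 went from 79.7 ± 12.5 to 28.4 ± 1.31 CPM, Cmpk2 from 7.53 ± 0.787 to 1.86 ± 0.233 CPM and Gbp6 from 21.3 ± 3.96 to 6.24 ± 1.52 CPM (SD, n = 3 each). Of 37 tested members 13 fell and 0 rose, with 18 lower adjusted over the list alone (camera adjusted p = 8.24e-08; adjusted p = 0.661 with an estimated correlation), and the median was -0.75, or -0.57 with the Y-linked term. In the inflammasome list, which holds the NLRP3 partners of NEK7, Il1a fell by 1.25 on the log2 scale, the 1 call of 17 and the 1 adjusted over the list alone, and its call ended without WT 2 (adjusted p = 0.108), iKO 2 (0.0515) or iKO 3 (0.0666). Nlrp3 itself had a log2 fold change of -1.11 (adjusted p = 0.0652), and camera did not call the list (adjusted p = 0.371). NF-kB and cytokine genes held 1 higher (Nfkbia) and 3 lower members of 22, also adjusted over the list alone (list adjusted p = 0.886), with Tnfaip2 falling from 54.7 ± 2.51 to 11.7 ± 5.26 CPM (SD, n = 3 each). The Nfkbia call ended without any 1 of the WT libraries or iKO 3 (adjusted p up to 0.0913, without WT 2). None of 17 MHC and antigen presentation genes was called, adjusted over the list alone 0 (list adjusted p = 0.886).

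Cell cycle genes showed few calls. Ccne1, cyclin E1, rose from 0.230 ± 0.0773 to 2.46 ± 0.613 CPM (SD, n = 3 each; adjusted p = 0.00202), while Rrm2 rose by 1.04 and E2f2 fell by 1.57 on the log2 scale. These were the 3 called members of 36 G1/S and DNA replication genes, also adjusted over the list alone (list adjusted p = 0.886). The Rrm2 call ended without WT 2 (adjusted p = 0.103), WT 3 (0.0551) or iKO 3 (0.0558), and the E2f2 call without WT 2, WT 3, iKO 1 or iKO 2 (up to 0.0993, without WT 3). Of 36 G2/M and mitosis genes 0 were called, adjusted over the list alone 0, with a median of -0.33 (list adjusted p = 0.0829; 0.0304 after the length correction). Among 28 centrosome and microtubule genes Tubb2a fell from 204 ± 58.4 to 34.7 ± 9.36 CPM (SD, n = 3 each), Tuba4a and Cdk5rap2 were also lower, and the same 3 counted adjusted over the list alone. Expected counts of all 3 were not whole in all 6 libraries, so their levels are less certain. The centrosome list was called lower (adjusted p = 0.0312; adjusted p = 0.729 with an estimated correlation), not without iKO 1 (0.144), not without iKO 2 (0.0801) and not with the Y-linked term (0.112). Tuba4a and Cdk5rap2 each lost their calls without WT 2 (adjusted p = 0.0676 and 0.17) and in at least 3 other fits that left out a library. Of 26 p53 targets and CDK inhibitors 5 rose and 2 fell, 7 and 3 adjusted over the list alone (list adjusted p = 0.192). Plk3 went from 16.3 ± 4.24 to 261 ± 141 CPM and Bbc3, which encodes PUMA, from 15.0 ± 1.29 to 4.33 ± 1.56 CPM (SD, n = 3 each). Among 29 apoptosis and necroptosis genes 2 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.886), with Bmf falling by 2.26 (SE 0.23) and Casp9 by 1.12 (SE 0.19) on the log2 scale.

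In the acetaminophen metabolism list, 6 of 9 tested glutathione S-transferase genes were called higher, and Gsta3, Gstp1 and Gstp2 were not called. Gsta1 went from 1.54 ± 0.713 to 16.1 ± 6.19 CPM and Gsta2 from 18.9 ± 1.32 to 69.8 ± 25.3 CPM (SD, n = 3 each). Both belong to a family of near-identical copies, so reads could be split between them. Gsta4, Gstm1, Gstm2, Gstm3 and Cyp2a5 also rose and the exporter gene Abcc2 fell. In all 7 of 32 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.661 with an estimated correlation). The list call ended with the Y-linked term (adjusted p = 0.197) and after the length correction (0.0981). The calls of Gstm1 and Gstm2 ended after the length correction (adjusted p = 0.0735 and 0.0784), with log2 fold changes from 0.87 to 0.64 and from 1.04 to 0.70. With the Y-linked term the Gsta1 call held and the other 5 ended, while their log2 fold changes of 0.87 to 1.89 (SE 0.16 to 0.28) became 0.78 to 1.85 (SE 0.26 to 0.44). When 1 library was left out, the Gstm1 call ended in all 6 fits (adjusted p up to 0.199), Abcc2 in 5 (up to 0.195), Gstm2 in 4 (up to 0.122), each highest without WT 2, and Cyp2a5 in 3 (up to 0.0686, without iKO 3). The main acetaminophen oxidase gene, Cyp2e1, was at 6380 ± 629 and 8027 ± 3018 CPM (SD, n = 3 each; adjusted p = 0.464). Nrf2 targets and glutathione synthesis genes held 4 higher and 2 lower members of 33, 5 and 2 adjusted over the list alone (list adjusted p = 0.138), with Gss higher by 0.99 (SE 0.18) and Gclc lower by 1.37 on the log2 scale. The Gclc call held only without iKO 1 (adjusted p up to 0.074, without iKO 2). Of 22 nuclear receptor targets 2 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.57), and Por, the electron donor of microsomal cytochromes P450, went from 282 ± 60.0 to 827 ± 98.6 CPM (SD, n = 3 each).

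The gluconeogenesis and amino acid lists were called higher, though most members were not called. Pck1, the gluconeogenic PEP carboxykinase, went from 891 ± 151 to 3535 ± 586 CPM and Tat, tyrosine aminotransferase, from 1011 ± 252 to 3159 ± 454 CPM (SD, n = 3 each). Of 29 gluconeogenesis and glycolysis genes 8 rose and Hk3 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.729 with an estimated correlation). The Hk3 call ended without WT 2, WT 3 or iKO 3 (adjusted p up to 0.0802, without WT 2). Of 34 urea cycle and amino acid genes 6 rose, among them Got1, Sds and Tat, and Gldc fell, also adjusted over the list alone (adjusted p = 0.0403; adjusted p = 0.776 with an estimated correlation). That call was lost without WT 1 (0.0698), iKO 1 (0.316) or iKO 2 (0.0555) and after the length correction (0.0981). Lipid lists were mixed and not called. Among 28 fatty acid and triglyceride synthesis genes 3 rose and 4 fell (3 and 5 adjusted over the list alone, list adjusted p = 0.703), with Gpam going from 253 ± 57.4 to 89.7 ± 9.72 CPM (SD, n = 3 each). Cholesterol biosynthesis had 3 of 25 lower, also adjusted over the list alone (list adjusted p = 0.371), with Insig1 falling from 515 ± 99.4 to 169.6 ± 16.3 CPM (SD, n = 3 each). PPARa targets had 2 higher and 1 lower of 40, also adjusted over the list alone (list adjusted p = 0.263), with Angptl4 higher by 2.88 (SE 0.44). Bile acid genes had 2 higher and 3 lower of 23, 3 and 4 adjusted over the list alone (list adjusted p = 0.915), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, going from 54.6 ± 22.0 to 196 ± 67.7 CPM (SD, n = 3 each).

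The heat shock, acute phase and immediate early lists were called higher, and the ER stress list was not called. Hspa8 went from 621 ± 83.3 to 2097 ± 229 CPM (SD, n = 3 each), Dnajb1 rose by 1.63 (SE 0.25) and Hsph1 by 1.05 (SE 0.16) on the log2 scale. In all 8 of 19 heat shock genes rose, 11 adjusted over the list alone (camera adjusted p = 2.59e-06; adjusted p = 0.611 with an estimated correlation). Of 32 acute phase genes 6 rose, 8 adjusted over the list alone, with Orm2 going from 155 ± 59.4 to 834 ± 161 CPM (SD, n = 3 each). Expected counts of Orm2 were not whole in all 6 libraries. Its call held whichever library was left out, while those of Orm1, Socs3, Lrg1, Mt1 and Mt2 did not (adjusted p up to 0.18, Socs3 without WT 2). The acute phase list was called (camera adjusted p = 0.000369, or 0.729 with an estimated correlation). Immediate early genes had 2 of 21 called higher, Ier3 and Fosl2, 8 adjusted over the list alone, and a median of 1.27 (camera adjusted p = 0.000369; adjusted p = 0.729 with an estimated correlation). The Fosl2 call ended without WT 1 (adjusted p = 0.0505), WT 2 (0.148) or WT 3 (0.122). Of 28 ER stress genes 5 rose and 2 fell, 6 and 2 adjusted over the list alone (list adjusted p = 0.173), with Herpud1 going from 131 ± 12.9 to 652 ± 203 CPM (SD, n = 3 each).

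Of 48 cytosolic ribosomal protein genes 15 were called higher and 37 adjusted over the list alone, with Rpl12 going from 158 ± 38.9 to 305 ± 49.3 CPM (SD, n = 3 each; camera adjusted p = 4.99e-10; adjusted p = 0.729 with an estimated correlation). Of 45 nuclear oxidative phosphorylation genes 12 were called higher and 27 adjusted over the list alone (camera adjusted p = 3.05e-07; adjusted p = 0.729 with an estimated correlation). These transcripts are short, and after the length correction their medians went from 0.66 to 0.19 and from 0.58 to 0.13, with neither list called (adjusted p = 0.0838 and 0.332). Every called gene of both lists lost its call in at least 3 of the 6 fits that left out 1 library (adjusted p up to 0.206, Rps24 without WT 2). Among them, the Rpl12 call ended without WT 1 (adjusted p = 0.0505), WT 2 (0.121), iKO 1 (0.0544) or iKO 3 (0.0674). None of 31 proteasome genes was called, adjusted over the list alone 0 (list adjusted p = 0.173). Mature hepatocyte genes had 5 higher, among them Cebpb and Foxa3, and 1 lower of 35, 6 and 1 adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.78 with an estimated correlation). That call was lost without iKO 1 (0.146) and after the length correction (0.0798). Zonation genes went both ways. The pericentral list had 3 higher and 5 lower of 20, also adjusted over the list alone (list adjusted p = 0.703), the lower ones including Axin2, Lgr5 and Rnf43, while Glul and Cyp2e1 were not called (adjusted p = 0.835 and 0.464). With the Y-linked term 0 pericentral members were called. The Lgr5 call ended without WT 2 (adjusted p = 0.0564) and the Rnf43 call in all 6 fits that left out 1 library (up to 0.12, without WT 2). The periportal list had 3 higher and 4 lower of 21, 4 and 5 adjusted over the list alone (list adjusted p = 0.886).

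**Figure D3:**
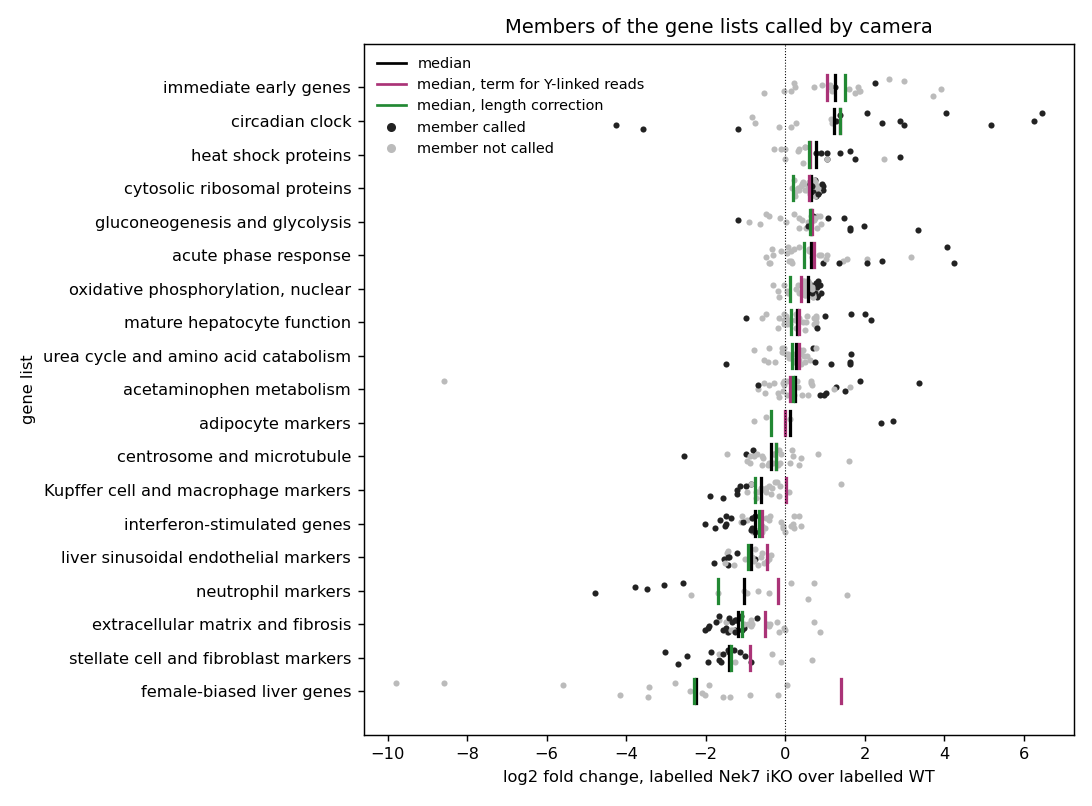
Log2 fold change, labelled Nek7 iKO over labelled WT, of the tested members of the 19 gene lists called by camera; black points were called. Lines mark the list median as fitted, with a term for Y-linked reads and after correction for transcript length. The stellate median goes from -1.42 to -0.88 with the Y-linked term and to -1.37 with the length correction. The ribosomal protein median goes from 0.66 to 0.19 with the length correction, and the female-biased median changes sign with the Y-linked term.

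Camera called 19 of 43 lists, 11 higher and 8 lower. With an estimated correlation it called 0, with 2 lists, the clock and heat shock proteins, at an unadjusted p under 0.05. Likewise the directional test of fry called 0, with 15 lists at an unadjusted p under 0.05.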

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

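The Y-linked and length settings were chosen after seeing the data. Nek7 stayed negative and short of the threshold under every alternative listed beforehand, from -0.01 without WT 1 to -0.46 without iKO 1, and was 0.019 after the transcript-length correction. The 2024 calls (962 higher, 1062 lower) stayed within 1.5 times under RLE and upper-quartile factors, no filter, DESeq2, limma-voom and the length correction. They became 184 (78 and 106) with the Y-linked term, 143 (66 and 77) in the 4 libraries with Y-linked reads and 164 (85 and 79) with the Y-linked term and the length correction; fewer samples per estimate lower these counts by construction, and other causes were not tested. Limma-trend called 421 genes higher on log2(FPKM + 1) and 427 on log2(FPKM + 0.1); the cause was not tested. Leaving out 1 library gave 491 to 1840 calls, 228 to 922 higher and 263 to 1096 lower, the lowest without WT 2. Of 109 named genes that were called, 65 were called in all 6 such fits and 34 with the Y-linked term.

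The 19 list calls ranged from 13 to 25 when 1 library was left out, and became 0 with an estimated correlation and 0 by fry, whose cause was not tested. The female-biased list turned to higher with the Y-linked term (adjusted p = 0.00132), in the 4 libraries (0.000931) and with both corrections (0.00108), the male-biased list, not called, was called lower with the Y-linked term (0.00213) and with both corrections (0.0001), and the oxidative phosphorylation list turned to lower with both corrections (0.719). Among single genes, Cyp2b13 became 0.36 with the Y-linked term and 0.25 with both corrections, Prlr 0.032 and Ndufa5 -0.089 with both corrections. Fabp4, not called, became -0.13 and -0.16 on the FPKM scales, -0.20 (without iKO 2) to 0.42 (without iKO 3) when 1 library was left out, -0.013 with the Y-linked term, -0.0061 in the 4 libraries, -0.36 after the length correction and -0.45 with both. Upper-quartile factors moved the median log2 fold change of all genes from -0.02 to -0.08.

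Livers with the same replicate number did not deviate together in all pairs (correlations 0.21, 0.22 and 0.05 across genes), and 3 of 6 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate block 1710 genes (772 higher, 938 lower) and 20 lists were called, and Nek7 was at -0.23. Depth limits genes near 1 CPM.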

Other observations

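The splits of the 6 libraries were planned; the other tests here were chosen after the results were seen. Terms in the deposited annotation described further groups. Genes lower in the livers labelled iKO included 28 of 86 basement membrane genes where 7.07 would come by chance (adjusted p = 1.55e-08 by a one-sided Fisher test), and 18 after the length correction (adjusted p = 0.000131). Tight junction genes were lower in 22 of 101 (8.30 by chance, adjusted p = 0.00131), and 18 after the length correction (adjusted p = 0.000977). Genes higher included 15 of 72 of ribosome biogenesis (5.17 by chance, adjusted p = 0.00535; 15 and 0.00107 after the length correction) and 11 of 44 of cysteine and methionine metabolism (3.16 by chance, adjusted p = 0.00652; 10 and 0.00731). Wnt and TGF-beta signaling terms were lower in 22 of 120 and 16 of 78 genes (adjusted p = 0.0327 each) and not enriched after the length correction (adjusted p = 0.881 and 0.763). With the Y-linked term none of these terms was enriched, in a fit with 184 calls.

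Of 66 called predicted genes without a symbol, 46 were higher and 20 lower. The 13 with a log2 fold change over 3, a bound set after the values were seen, reached 3.87, and 12 of them had counts that were not whole in all 6 libraries. Cnbd2 was at 45.6 ± 11.2 CPM in WT and 532 ± 133 CPM in the livers labelled iKO (SD, n = 3 each; adjusted p = 0.000281), and its transcript shares 351 bases at 96.0% identity with predicted gene Gm42031 and 282 bases at 95.4% with Gm43305.

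The clock genes stood apart between the labelled groups, with a median absolute log2 fold change of 2.99 over the 13 called members. A transcript-length trend is argued against, since the median was 3.22 after the length correction and all 13 were still called. A difference made by WT 2 and WT 3 is argued against as the whole cause, since the median was 3.52 with the Y-linked term, though that contrast rests on WT 1 as the only WT library of its kind. Livers taken at different times of day in the 2 groups could give the pattern: 15 of 15 clock genes placed in 2 opposite phases had the sign of their phase. Of these 12 were called; Nr1d1, Clock and Nfil3 were not. The phases were assigned after the values were seen, and not every tested clock gene was placed in a phase. The labels give no hour of collection, and an effect of the knockout on the clock would look alike, so these cannot be told apart. A difference in hour could also bear on calls outside the clock list, the metabolic lists included, which was not tested.

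Lower non-parenchymal markers and higher ribosomal protein and oxidative phosphorylation genes came together. The length trend may account for most of the latter, with medians of 0.19 and 0.13 after the correction, though the correction would also remove a true rise of short genes; it is argued against for stellate markers, whose median stayed at -1.37. A lower share of every non-parenchymal cell was not settled. T, NK and cholangiocyte markers at 1 CPM or more (26) had a median 1.51 above that of 20 stellate markers (permutation p = 2e-05). That test shuffled genes, which are not independent, and took the stellate list after its fall was seen. Kupffer cell, endothelial and neutrophil markers, with medians of -0.61, -0.86 and -1.04, were left out of it. The values show only that T, NK and cholangiocyte markers did not fall with the stellate markers. The mix of WT libraries, in which WT 2 and WT 3 read as female, may account for the Kupffer cell part (median 0.013 with the Y-linked term). For the stellate part this mix cannot be told apart from other causes. There the median was -0.88 and 3 of 15 called members kept their call, with 1 WT library of that kind. Fewer stellate cells or a lower expression in them stays open, untested.

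Nek7 was near its WT level in the livers labelled iKO. A swap of libraries between the groups cannot be told apart from none. Over all exchanges of labels the lowest Nek7 ratio was 68.5%, with WT 3, iKO 2 and iKO 3 as the low group. Going 2 SE below that gives 49.8%, but the SE is that of the groups as labelled. That value is therefore no interval for the exchanged groups and cannot decide the question. By chi-square of counts per degree of freedom, WT 1 was nearer iKO 1 and iKO 2 (164 and 166) than WT 2 and WT 3 (182 and 200). It was farthest from iKO 3 (235). Abundant genes weigh most in this measure, among them sex-biased ones such as Mup20 (6510 CPM in WT 1, 162 CPM in WT 2). It therefore does not show likeness over all genes. WT 1 also holds Y-linked reads like the libraries labelled iKO. By the same measure iKO 1 was nearest iKO 2 (148), with iKO 2 and iKO 3 at 41.3 and WT 2 and WT 3 at 38.0. The first principal component (53.3% of variance) put WT at -17.7, -53.2 and -47.1 and those labelled iKO at 56.9, 27.5 and 33.5. A fall hidden by WT 2 and WT 3 cannot be told apart from none, with -0.55 (SE 0.29, adjusted p = 0.372) under the Y-linked term. A deletion of a part that leaves the rest of the transcript to be counted could give a gene total at 86.1% of WT, and without reads per exon it cannot be told apart from an incomplete deletion.

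The number of splits of the 6 libraries, 10, is too few for a share under 0.05. The real split called 2024 genes, and the highest of the other 9 called 0 by edgeR. At an unadjusted p under 0.05 these had at most 853 genes and the real split 4362. As many calls came in 1 of 10 splits. Each of the other 9 mixes the labels in its groups, so a label difference counts there as spread within a group and lowers the calls by construction. For lists, 4 of 10 splits gave as many as the real 19, the highest of the others being 27, so calls with the preset correlation also arise between sets that mix the 2 labels.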
